A study of Mus musculus with 6 samples.

How the data were processed

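The study measured RNA of CD4+ T cells of pooled lymph nodes in 3 adult and 3 infant mice, which the series describes as naive cells with 1 mouse per biological replicate. Per the labels' protocols, 1000 cells per library were sorted 2 times in succession into lysis buffer, polyadenylated RNA was copied into cDNA from an oligo(dT) primer, the cDNA was amplified by PCR, fragmented with a transposase (Nextera XT) and sequenced in paired reads of 25 bases on a NextSeq 500. This protocol does not mark strand, so reads of a gene and of an antisense partner cannot be told apart, and no molecular identifiers were used, so that counts include PCR copies. Reads of 25 bases often match several members of a gene family.

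Per the submitters' processing notes, reads were aligned with STAR 2.5.4 and counted with featureCounts on the mouse build mm10. The version of featureCounts, the annotation release and the treatment of reads that match several places are not given in the sources used here. The deposited table holds raw counts per gene symbol for the 6 libraries, whole numbers that were not normalized, with 52997 genes, of which 39470 had a count in any library. It has no column of another sample and no line of unassigned reads. Positions, biotypes, exon lengths and GC content came from a GENCODE annotation of the same build, and 49330 symbols (93.1%) had a match in it.

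Library totals ran from 3421253 to 4887371 counts. A floor of 3 counts corresponded to 0.628 to 0.852 CPM in the single libraries, for counting error only. The gene with most counts in each library was Gm42418, a gene that overlaps ribosomal RNA, with 3.91% to 7.06% of counts. No pair of replicates agreed within counting noise (chi-square per degree of freedom 5.44 to 13.4), which does not tell separate mice from separate amplifications of the same cells.

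Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after filterByExpr (minimum count 10, minimum total 15), which kept 11681 genes, with TMM factors of 0.963 to 1.07 and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are infant over adult, and each SE is the absolute log2 fold change divided by the square root of F. CPM used the total of tested genes times the TMM factor. The biological coefficient of variation was 0.184. Because age was the only difference between the groups in the labels, the fit had no covariate.

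Gene lists were 39 sets of symbols or symbol patterns from textbook knowledge, of which 36 had at least 3 tested members. They were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation and fry served as alternatives. Shares of counts in other-cell lists, depth and detected genes were compared by exact permutation tests over the 20 assignments, two-sided, which cannot give a p under 0.1.

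The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where a sentence says otherwise. Genes were named if they were among the 12 of largest change in each direction at an adjusted p under 0.05, with groups that did not overlap and a mean of at least 20 CPM in the higher group. Named too were the up to 4 members of smallest p among those passing in each list, or the 2 of highest expression where none passed, and 17 genes of prior interest, among them Foxp3, Cd4, Cd3e, Il7r, Cd44, Izumo1r, Nt5e, Il1rl1, Nr4a1, Egr2, Lin28b, Igf2bp3, Dntt, Cd24a, Ly6c1 and Mki67. Some genes this rule names are not reported here.

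Alternatives for the count of genes and for the lists were DESeq2 size factors, upper-quartile factors, library totals, no filter, a stricter filter (10 counts in 3 libraries and a mean of 20), the replicate number as a block, thinning of all libraries to 3421253 counts, removal of ribosomal protein, mitochondrial, T cell receptor, haemoglobin and sex-linked genes, and leaving out each library in turn. For the count of genes there were also DESeq2 1.42.0, limma-voom with and without quality weights, an adjusted p of 0.01, a 2-fold minimum and a test against 1.5-fold. Corrections for exon length and GC content and a fit without adult replicate 2 and infant replicate 3 were added after the data had been seen. The GC and length trends were smoothed with a span of 0.3.

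The fit was tested on simulated counts for the 11681 genes with the means and library sizes of the real libraries and 200 changed genes. Of the changed genes that passed the filter it recovered 66.3% of 2-fold and 87.0% of 4-fold changes and called 4 unchanged genes. In the same simulation a list lowered by 0.5 on the log2 scale had a camera p (limma) of 2.16e-19 with the preset and a p of 4.50e-04 with an estimated correlation, and an unchanged list had 0.387. Genes were drawn independently of one another, so the simulation does not show how either version handles correlated genes. Nothing in the labels gave a sequencing or library batch.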

Results

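Messenger RNA was sequenced from naive CD4+ T cells of pooled lymph nodes from infant mice aged 10 days and adult mice aged 7 weeks. The mice were Foxp3-GFP animals on the C57BL/6 background, a strain in which regulatory T cells that express the transcription factor Foxp3 carry a green fluorescent reporter. Each group held 3 mice, and each library came from 1000 cells of 1 mouse sorted through the gate 2 times in succession. The library titles call the cells Tconv, read here as conventional CD4+ T cells, and the markers of the gate are not given in the sources used here. The adult libraries held 4293687, 3421253 and 4887371 counts and the infant libraries 4739304, 4115742 and 4256735, so that depth did not separate the ages (exact permutation test, two-sided p = 0.9, with 0.1 the smallest p that 3 against 3 allows). Adult replicate 2 had a count at 36373 genes, against 17992 to 21840 in the other 5 libraries.

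The comparison asked how the transcriptome of lymph node CD4+ T cells at 10 days of age differed from that of adult mice. The T cell identity genes were alike in level. Cd4 was at 979.9 ± 136 CPM (counts scaled to library size, mean ± SD, n = 3) in adult and 867 ± 10.4 in infant libraries, and Cd3e, a chain of the T cell receptor complex, at 615 ± 20.6 and 599 ± 34.7. Foxp3 was at 5.60 ± 0.968 and 7.61 ± 1.39 CPM (log2 fold change 0.45 ± 0.40, SE, edgeR adjusted p = 0.626). Its infant values all lay above its adult values (exact permutation test, two-sided p = 0.1, the smallest possible), so a small difference in Foxp3 stays undecided. Against this background infant cells had less RNA of MHC class I, interferon-stimulated, NF-kB target and ribosomal protein genes, and more RNA of cell-cycle genes and of the fetal RNA-binding protein gene Igf2bp3. The changes of these 5 lists passed limma camera with a preset correlation, and no list passed with an estimated correlation (lowest adjusted p = 0.384).

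Of 11681 genes tested, 425 differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 178 higher and 247 lower in infant cells. Of these, 85 were higher and 99 lower by at least 2-fold. The 3 infant values lay wholly above or wholly below the 3 adult values in 22.8% of tested genes, where chance gives 10%. The first principal component carried 35.5% of the variance and separated the ages, and the second (21.9%) set adult replicate 2 apart from the other 5 libraries (−45.2 against −0.260 to 22.5). Over the 500 most variable genes adult replicate 2 also lay apart from the other adults on the first component (−3.22 against −23.5 and −23.6). Correlations of log2 CPM were 0.953 to 0.969 between libraries of the same age and 0.942 to 0.950 between ages. The count of 425 rested on all libraries but 1: it was 185 without adult replicate 1, 208 without adult replicate 3, and 176, 139 and 189 without infant replicates 1, 2 and 3, but 488 without adult replicate 2.

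**Figure D1:**
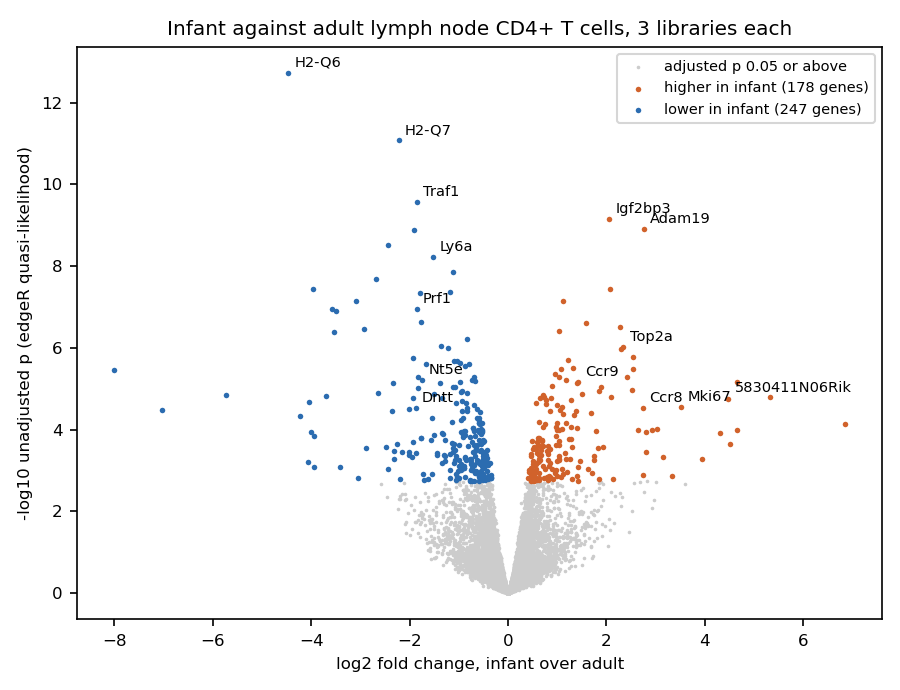
Each point is 1 of 11681 tested genes, with the log2 fold change of infant over adult on the x axis and −log10 of the unadjusted edgeR p on the y axis. Coloured points are the 178 genes higher and 247 genes lower in infant cells at an adjusted p under 0.05, with H2-Q6 and H2-Q7 at the top left and Igf2bp3 and Adam19 at the top right.

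Among genes of at least 20 CPM in the higher group, the fall in infant cells was steepest for H2-Q6, a non-classical MHC class I gene on chromosome 17 (35424850 to 35430055, mm10). It had 286, 209 and 264 CPM in the adult and 9.84, 12.8 and 11.6 in the infant libraries, which is 22.2-fold lower in infant cells (log2 fold change −4.47 ± 0.17, edgeR adjusted p = 2.19e-09). Its neighbours H2-Q5 (chromosome 17, 35394126 to 35397800, annotated as a polymorphic pseudogene) and H2-Q7 (35439155 to 35443773) fell by 3.96 ± 0.37 and 2.22 ± 0.11 on the log2 scale. The antiviral genes Oas1a and Oasl1 had log2 fold changes of −2.92 ± 0.33 and −1.94 ± 0.25. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, had a log2 fold change of −3.09 ± 0.31, and Epas1, which encodes the hypoxia-inducible factor HIF-2α, of −2.64 ± 0.40. Tbc1d30, Fgf13, Tanc1, Tmie and Rab20, which have no single common function, had −3.57 ± 0.37, −3.49 ± 0.36, −2.67 ± 0.24, −2.43 ± 0.19 and −2.34 ± 0.34. These 12 genes had adjusted p of 2.19e-09 to 0.00213 and kept their calls without any single library. The H2-Q and Oas genes are close copies of one another, and how 25-base reads that match several copies were counted is not given in the sources used here, so the values of single family members are uncertain.

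In the other direction, Adam19, a membrane metalloprotease gene on chromosome 11 (46055992 to 46147343), had 20.8 ± 7.65 CPM in adult and 139 ± 1.37 in infant libraries (log2 fold change 2.76 ± 0.20, edgeR adjusted p = 2.49e-06). Ccr8, a chemokine receptor, rose by 2.74 ± 0.46 and Plag1, a zinc-finger transcription factor of fetal tissues, by 2.54 ± 0.33. Nedd4, an E3 ubiquitin ligase, rose by 2.54 ± 0.34, the linker histone gene H1f0 by 2.51 ± 0.38 and Top2a, the DNA topoisomerase of dividing cells, by 2.35 ± 0.29. Nebl (actin binding), Itga7 (a laminin-binding integrin), Capn3 (a calpain protease) and Tfpi (an inhibitor of coagulation) rose by 2.42 ± 0.34, 2.29 ± 0.28, 2.28 ± 0.26 and 2.09 ± 0.33. The neighbouring scavenger receptor genes 5830411N06Rik and Cd163l1 on chromosome 7 rose by 4.48 ± 0.71 and 3.03 ± 0.57. They are close copies, and their counts in adults were 12 and 31 in all. The 12 came from adult replicate 2 alone, so without that library the counts do not fix the size of the change of 5830411N06Rik. Leaving out 1 library gave edgeR log2 fold changes of 3.82 to 9.66 for that gene. The call for Cd163l1 was lost without infant replicate 2 or 3 (adjusted p at most 0.0556), and the calls for both genes were lost with DESeq2 (adjusted p = 0.112 for Cd163l1). Receptors of this kind are known from gamma-delta T cells, whose constant-region gene Trdc, looked up after these values were seen, did not pass (log2 fold change −0.45 ± 0.53, adjusted p = 0.730). With that SE, Trdc does not decide whether the share of such cells differed.

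**Figure D2:**
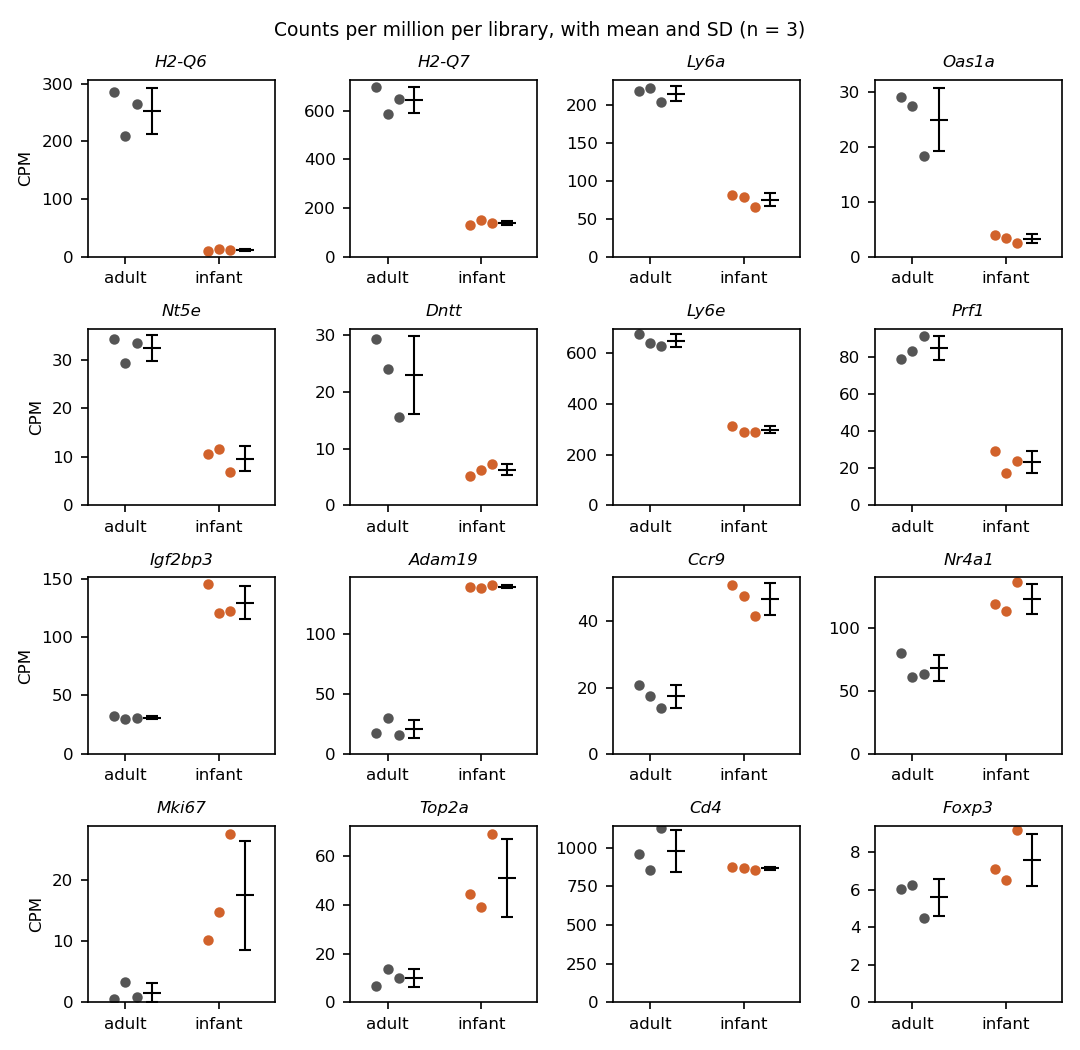
Each panel shows the CPM of 1 gene in the 3 adult (grey) and 3 infant (orange) libraries, with the mean and SD in black (n = 3). H2-Q6, H2-Q7, Ly6a, Oas1a, Nt5e, Dntt, Ly6e and Prf1 were lower and Igf2bp3, Adam19, Ccr9, Nr4a1, Mki67 and Top2a higher in infant libraries, and Cd4 and Foxp3 did not pass the test.

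MHC class I genes were lower in infant cells. Of 18 tested members, 9 fell, 0 rose and 9 did not pass, and 12 fell when adjusted over the list alone (median log2 fold change −0.40, limma camera adjusted p = 4.77e-08, but adjusted p = 0.384 with an estimated correlation). Beside H2-Q6 and H2-Q7, the shared light chain B2m went from 2889 ± 281 to 1989.7 ± 127 CPM (log2 fold change −0.54 ± 0.10) and the classical heavy chain H2-K1 from 6329.5 ± 943 to 4247 ± 338 (−0.58 ± 0.11). The calls for B2m and H2-K1 were lost without adult replicate 1 or infant replicate 1 or 2, and for H2-K1 also without adult replicate 3 (edgeR adjusted p at most 0.0690 and 0.108). The count of 9 fell to 2, 3, 2, 3 and 5 without adult replicates 1 and 3 and infant replicates 1, 2 and 3.

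Interferon-stimulated genes were lower as well, with 8 of 42 members down, 0 up and 34 not passing, and 18 down when adjusted over the list alone (median −0.32, camera adjusted p = 3.20e-07, adjusted p = 0.398 with an estimated correlation). Oas2 fell by 1.35 ± 0.21 and the cell-surface gene Ly6e by 1.12 ± 0.10 on the log2 scale. The list of interferon-induced GTPases and antigen-processing genes had 2 of 25 members down, Gbp5 (−1.33 ± 0.25) and Iigp1 (−1.29 ± 0.29), and 4 adjusted over the list alone (median −0.23, camera adjusted p = 0.00947, adjusted p = 0.384 with an estimated correlation). That list did not pass without adult replicate 1 or infant replicate 3 (camera adjusted p = 0.0635 and 0.0545), and its median was −0.15 without infant replicate 1. Gbp5 was lost without adult replicate 3 or infant replicate 2 and Iigp1 without adult replicate 1 or infant replicate 2 or 3 (edgeR adjusted p at most 0.0611 and 0.157). The interferon-stimulated count was 5 without infant replicate 1 or 3, with the list past the test each time.

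NF-kB target genes followed the same direction: 6 of 16 fell, 0 rose and 10 did not pass, with 7 down adjusted over the list alone (median −0.45, camera adjusted p = 9.11e-04, adjusted p = 0.384 with an estimated correlation). Traf1, a signalling adaptor of TNF receptors, went from 262 ± 17.5 to 72.3 ± 6.94 CPM (log2 fold change −1.86 ± 0.12, edgeR adjusted p = 1.05e-06). Icam1, an adhesion molecule, Cd83, a surface glycoprotein of activated cells, and Nfkbia, the NF-kB inhibitor, had log2 fold changes of −0.99 ± 0.20, −2.16 ± 0.46 and −0.57 ± 0.10. Each of these 3 lost its call without adult replicate 1 or infant replicate 2 or 3, Icam1 also without adult replicate 3, and Cd83 also without adult replicate 2 or infant replicate 1 (adjusted p at most 0.0790, 0.113 and 0.0668). The count of 6 was 1, 3, 4, 1 and 2 without adult replicates 1 and 3 and infant replicates 1, 2 and 3.

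Genes that rise as T cells mature after leaving the thymus were lower in infant cells, with 5 of 17 down and 0 up (median −0.15, mean −0.65, camera adjusted p = 0.00319, adjusted p = 0.384 with an estimated correlation). Adjusted over the list alone, 6 were down and 1 up. Leaving out 1 library gave a median of −0.27 (without adult replicate 3) to −0.089 (without adult replicate 1), with the list past the test each time. The 5 genes were H2-Q6, H2-Q7, Ly6a, Ly6e and Nt5e, of which H2-Q6 and H2-Q7 also stand in the MHC class I list and Ly6e in the interferon-stimulated list. Ly6a, which encodes the surface antigen Sca-1, had 215 ± 10.1 CPM in adult and 75.3 ± 8.55 in infant libraries (log2 fold change −1.51 ± 0.12, edgeR adjusted p = 8.59e-06). Nt5e, which encodes the ectoenzyme CD73, had 32.3 ± 2.67 and 9.61 ± 2.53 CPM (−1.75 ± 0.25, adjusted p = 0.00142). Il7r (−0.12 ± 0.14) and Ly6c1 (−0.21 ± 0.18) did not pass.

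Genes of thymocytes and recent thymic emigrants went both ways. Of 14 tested, Ccr9, a thymic and intestinal homing receptor, rose (17.4 ± 3.48 to 46.7 ± 4.74 CPM, log2 fold change 1.43 ± 0.21, edgeR adjusted p = 0.00147), and Dntt, the polymerase that adds untemplated nucleotides to rearranging antigen receptor genes, fell (29.3, 24.1 and 15.6 CPM in adult and 5.23, 6.29 and 7.25 in infant libraries, −1.88 ± 0.31, adjusted p = 0.00363). Adjusted over the list alone, 5 rose and 1 fell (median 0.26, camera upward, adjusted p = 0.0384, adjusted p = 0.384 with an estimated correlation). The list did not pass without adult replicate 2 or infant replicate 2 (camera adjusted p = 0.0577 and 0.0549), nor with a stricter filter or after thinning to equal depth (0.274 and 0.0767). Its median was 0.59, 0.57, 0.79 and 0.65 without adult replicates 1, 2 and 3 and infant replicate 3, and 2 members rose without adult replicate 2. Cd24a, which did not pass the filter on low counts, had 0.48, 2.27 and 0.64 CPM in the adult and 3.35, 10.2 and 2.17 in the infant libraries. T cell receptor variable segments had 2 of 52 members up, Trbv19 (1.00 ± 0.18) and Trbv20 (0.90 ± 0.22), 0 down, and 3 up adjusted over the list alone (median 0.22, camera adjusted p = 0.0127, adjusted p = 0.384 with an estimated correlation). The segment list did not pass without adult replicate 2 or infant replicate 1 or 2 (camera adjusted p = 0.101, 0.0716 and 0.0549), and its median was 0.073 without infant replicate 1. Trbv20 lost its call without any of the 6 libraries and Trbv19 without infant replicate 1 or 2 (edgeR adjusted p at most 0.147 and 0.0611). Gut-homing genes had Ccr9 up and 0 of 5 down, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.115, but 0.0301 without infant replicate 3).

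Among 8 tested genes of fetal and neonatal lymphocytes, Igf2bp3, an RNA-binding protein gene of fetal tissues on chromosome 6 (49085223 to 49214957), rose from 31.1 ± 1.45 to 129 ± 13.9 CPM (log2 fold change 2.06 ± 0.14, edgeR adjusted p = 2.04e-06). It rose also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.470). Lin28b, its upstream partner in fetal blood cells, was too low to test, with 4.83 CPM in adult replicate 2 and at most 1.21 in the other 5 libraries. Il1rl1, the receptor of interleukin 33, had a count in adult replicate 2 alone (3.69 CPM). That library had counts over many otherwise silent genes, with 1.85 counts per kb of exon over untested autosomal protein-coding genes. Its 17 counts of Lin28b (9065 bases of exon) and 13 of Il1rl1 (6894 bases) lay near that density. They therefore do not show expression of either gene. Of 4 imprinted genes Igf2r rose (0.68 ± 0.14), with 2 up adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0897). Igf2r lost its call without adult replicate 1 or infant replicate 1 or 2 (edgeR adjusted p at most 0.0830).

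As a list, cell-cycle genes were higher in infant cells. Of 33 tested, 4 rose, 0 fell and 29 did not pass, with 8 up and 2 down adjusted over the list alone (median 0.88, camera adjusted p = 9.11e-04, adjusted p = 0.404 with an estimated correlation). The 2 down were Cdt1 (−0.46 ± 0.16) and Tyms (−0.89 ± 0.31). Among DNA replication genes of the Mcm family, Mcm3 was at 0.34 ± 0.17, and Mcm2, Mcm4, Mcm5, Mcm6 and Mcm7 lay from −0.34 to −0.0096. None of these Mcm genes passed over all genes. Mki67, the marker of cycling cells, had 1.58 ± 1.59 CPM in adult and 17.5 ± 8.96 in infant libraries (log2 fold change 3.52 ± 0.58, edgeR adjusted p = 0.00352), and Top2a had 10.1 ± 3.55 and 51.0 ± 16.1. The mitotic genes Nusap1 and Ccna2 rose by 2.80 ± 0.60 and 3.34 ± 0.84, and their calls were lost without any single library other than adult replicate 2 (adjusted p at most 0.144 and 0.268). Adult replicates 1 and 3 held 0 and 1 counts of Ccna2, so the size of its change rests on adult replicate 2. Adult replicate 2, which had counts over many otherwise silent genes, held the highest adult level of Mki67 (3.41 against 0.48 and 0.85 CPM) and of Top2a (13.6 against 6.55 and 10.0). Without it 11 of 37 tested cell-cycle genes rose, whereas 2 rose without adult replicate 1 or 3 or infant replicate 3, and the median was 0.57 without infant replicate 3. Without both adult replicate 2 and infant replicate 3 the median was 0.42, with 6 of 31 up and 1 down. With the stricter filter it was 0.51. Of 10 histone genes H1f0 rose and 0 fell, with 2 up and 4 down adjusted over the list alone (camera adjusted p = 0.217).

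Genes induced by T cell receptor stimulation were higher, with 3 of 22 up and 0 down, and 5 up adjusted over the list alone (median 0.27, camera adjusted p = 0.00406, adjusted p = 0.384 with an estimated correlation). The nuclear receptor Nr4a1 went from 68.1 ± 10.4 to 123 ± 11.9 CPM (log2 fold change 0.85 ± 0.14, edgeR adjusted p = 0.00394), the transcription factor Egr1 from 68.7 ± 7.03 to 111 ± 10.7 (0.69 ± 0.14, adjusted p = 0.0116) and the activation marker Cd69 from 213 ± 47.0 to 325 ± 20.3 (0.61 ± 0.14, adjusted p = 0.0255). Egr2 did not pass (0.0061 ± 0.23). The list did not pass without adult replicate 3 (camera adjusted p = 0.0692) and had 1 member up without infant replicate 1 or 3. Its median was 0.17 and 0.15 without infant replicates 1 and 3 and 0.44 without adult replicate 2. Egr1 lost its call without adult replicate 1 or infant replicate 1 or 3, and Cd69 without adult replicate 3 or any infant library (edgeR adjusted p at most 0.0800 and 0.139). Cd69 also lost it with GC correction (adjusted p = 0.0519).

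Immediate-early and heat-shock genes did not rise with them: 4 of 17 fell and 0 rose, also when adjusted over the list alone, and the list did not pass (median −0.31, camera adjusted p = 0.0507). It passed without adult replicate 3 or infant replicate 3 (camera adjusted p = 0.0304 and 0.0423), and its median was −0.14 without adult replicate 1. The 4 were Klf6 (−0.97 ± 0.13), Nfkbia, Btg2 (−0.55 ± 0.11) and Junb (−0.49 ± 0.12). Klf6 kept its call without any single library, Btg2 lost it without adult replicate 1 or infant replicate 2 or 3, Nfkbia without the same 3, and Junb without any of the 6 (edgeR adjusted p at most 0.105, 0.0668 and 0.199). Genes linked to T cell anergy, a state of lasting unresponsiveness, went both ways. Of 21 tested, Nr4a1 rose, and Nt5e and Ndrg1 (−1.50 ± 0.29), a gene of the cellular stress response, fell, with 1 up and 3 down adjusted over the list alone (median −0.14, from −0.24 without infant replicate 1 to −0.012 without adult replicate 2, camera adjusted p = 0.292). Ndrg1 lost its call without adult replicate 3 (adjusted p = 0.0519). Izumo1r, the folate receptor 4 used as an anergy marker, had 145 ± 17.8 CPM in adult and 116 ± 18.5 in infant libraries and did not pass (−0.32 ± 0.14, adjusted p = 0.260).

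Cytosolic ribosomal protein genes were lower in infant cells. Of 84 tested, 24 fell, 1 rose and 59 did not pass, with 53 down and 1 up adjusted over the list alone (median −0.34, camera adjusted p = 2.67e-15, adjusted p = 0.384 with an estimated correlation). All 90 ribosomal protein genes with a symbol in the table, 6 of them untested, took 56159 ± 1047 CPM in adult and 45441 ± 2669 in infant libraries (exact permutation test, p = 0.1, the smallest possible). Rps15, Rpl26, Rps24 and Rpl10 had log2 fold changes of −0.68 ± 0.10, −0.74 ± 0.11, −0.67 ± 0.10 and −0.56 ± 0.10. The member that rose was the copy Rps4l (3.14 ± 0.70), named after its value was seen, and its call was lost without any single library other than adult replicate 2 (edgeR adjusted p at most 0.180). The count of 24 was 9, 11, 4, 7 and 8 without adult replicates 1 and 3 and infant replicates 1, 2 and 3, with the list past camera each time. Ribosomal protein genes have many processed copies in the genome, so single members are uncertain.

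Ribosome biogenesis and Myc target genes moved up, though 1 member passed, Ldha, the lactate dehydrogenase (0.42 ± 0.10). Adjusted over the list alone, 5 of 25 rose and 0 fell (median 0.22, camera adjusted p = 0.00930, adjusted p = 0.399 with an estimated correlation). The list did not pass without adult replicate 2 or infant replicate 3 (camera adjusted p = 0.0694 and 0.136, with a median of 0.098 without the latter), and Ldha lost its call without any library other than adult replicate 2 (edgeR adjusted p at most 0.186). Cholesterol synthesis genes were lower as a list of 23 (median −0.24, camera adjusted p = 0.00956, adjusted p = 0.384 with an estimated correlation). That list did not pass without adult replicate 2 or infant replicate 1 (camera adjusted p = 0.0694 and 0.0763, with a median of −0.14 without the latter). Glycolysis genes had Tpi1 (1.00 ± 0.16) and Ldha up and the kinase gene Pdk1 (−0.59 ± 0.12) down among 21, with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.522). Pdk1 lost its call without adult replicate 1 or 3 or infant replicate 1 or 2 (edgeR adjusted p at most 0.122). Nuclear-encoded respiratory chain genes had Atp5g3 up (0.53 ± 0.11) and Cox7a2l (−0.59 ± 0.10) and Ndufa6 (−0.55 ± 0.13) down among 76, the same counts adjusted over the list alone (camera adjusted p = 0.845). Atp5g3 lost its call without adult replicate 1 or 3 or infant replicate 2 or 3, Cox7a2l without infant replicate 1 or 2, and Ndufa6 without any of the 6 (edgeR adjusted p at most 0.126, 0.0611 and 0.160). None of 9 mitochondrially encoded genes passed over all genes, and 1 rose adjusted over the list alone (mt-Co1 0.14 ± 0.11, mt-Nd5 0.26 ± 0.10, camera adjusted p = 0.110).

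**Figure D3:**
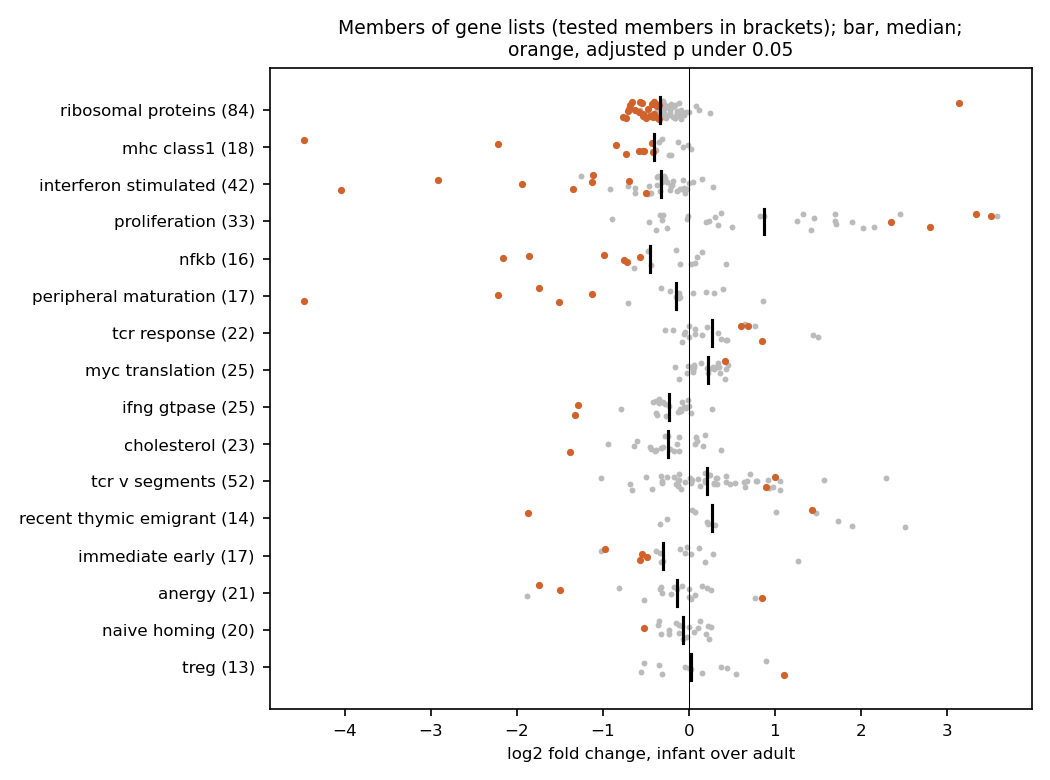
Each point is a tested member of a gene list, placed by its log2 fold change of infant over adult, with members at an adjusted p under 0.05 in orange and the median of the list as a black bar. The upper 12 lists passed camera with a preset correlation, none of them with an estimated one, and the lower 4 lists did not pass.

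The 20 naive identity and lymph node homing genes did not pass as a list (camera adjusted p = 0.470). Of 14 memory and effector genes, Ahnak (1.58 ± 0.17), Vim (0.77 ± 0.12), the intermediate filament vimentin, and Lgals1 (0.97 ± 0.19), galectin 1, rose and 0 fell, with 5 up and 5 down adjusted over the list alone (camera adjusted p = 0.768). Lgals1 lost its call without adult replicate 1 or 3 or infant replicate 2 (edgeR adjusted p at most 0.0952), and Cd44 did not pass (0.38 ± 0.20). T helper 1 genes had the cytokine receptor chains Il12rb1 up (1.83 ± 0.38) and Il18r1 down (−0.92 ± 0.18) among 5, with 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.462). Il12rb1 lost its call without adult replicate 3 or any infant library and Il18r1 without infant replicate 2 or 3 (edgeR adjusted p at most 0.0957 and 0.0643). T helper 2 genes had Ccr8 up and 0 down among 5, with 2 up adjusted over the list alone (camera adjusted p = 0.283). None of 6 T helper 17 and follicular helper genes passed in either adjustment (Icos −0.020 ± 0.16, Sh2d1a −0.062 ± 0.14, camera adjusted p = 0.249). Of 13 regulatory T cell genes, the receptor gene Gpr83 rose (1.11 ± 0.19), with 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.217), and lost its call without infant replicate 2 (edgeR adjusted p = 0.0565).

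GTPases of the immunity-associated protein family had Gimap7 (−1.09 ± 0.14) and Gimap3 (−0.50 ± 0.11) down and 0 up among 9, the same adjusted over the list alone (camera adjusted p = 0.0537). Without adult replicate 2 the list passed (median −0.22, camera adjusted p = 0.00458). Gimap3 lost its call without any library other than adult replicate 2 (edgeR adjusted p at most 0.166). Glucocorticoid-responsive genes had Txnip up (0.82 ± 0.18) and Nfkbia down among 14, also adjusted over the list alone (camera adjusted p = 0.768), and Txnip was lost without adult replicate 3 or any infant library (edgeR adjusted p at most 0.116). None of 16 TGF-beta pathway genes passed in either adjustment (Tgfbr2 0.29 ± 0.23, Tgfbr3 −0.15 ± 0.12, camera adjusted p = 0.768). None of 20 apoptosis and p53 genes passed over all genes, and 1 rose adjusted over the list alone (Casp8 0.10 ± 0.10, Trp53 −0.047 ± 0.13, camera adjusted p = 0.912).

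Markers of natural killer, NKT and gamma-delta T cells had 2 of 4 tested down in either adjustment and 0 up (camera adjusted p = 0.0537, but 0.0461 and 0.0253 without adult replicate 3 and infant replicate 3). Prf1, the pore-forming protein of cytotoxic cells, went from 84.7 ± 6.40 to 23.3 ± 5.97 CPM (log2 fold change −1.86 ± 0.19, edgeR adjusted p = 7.34e-05), and the receptor chain Klrd1 from 19.7 ± 5.74 to 7.78 ± 0.900 (−1.33 ± 0.31). Klrd1 lost its call without any library other than adult replicate 3 (adjusted p at most 0.138). All 16 markers of this list summed to 123 ± 9.99 and 46.8 ± 8.54 CPM (exact permutation test, p = 0.1), and most of that was Prf1 and Klrd1. The other tested members, Cd160 (0.82 ± 0.46) and Trdc (−0.45 ± 0.53), did not pass. B lineage markers summed to 799 ± 57.5 and 758 ± 49.4 CPM (exact p = 0.3), most of it Ighm (769.7 ± 68.6 and 716 ± 67.7), while Cd79a was at 6.55 ± 0.275 and 5.36 ± 0.725, and none of 5 tested passed in either adjustment (camera adjusted p = 0.906). Myeloid markers summed to 403 ± 26.1 and 329.7 ± 29.4 CPM (exact p = 0.1), with Fcgr3, an Fc receptor gene, up from 2.26 ± 0.760 to 8.13 ± 1.44 among 3 tested, and 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.147). Fcgr3 made up little of that sum. Of the other tested members, Itgam had 0.80 ± 0.35 and Ctss −0.32 ± 0.11. Dendritic cell markers summed to 101 ± 27.9 and 95.9 ± 16.0 CPM (exact p = 0.8), with none of 3 passing in either adjustment (Bst2 −0.024 ± 0.18, Zbtb46 0.33 ± 0.33, camera adjusted p = 0.688). Erythroid markers summed to 31.4 ± 7.05 and 36.6 ± 6.93 CPM (exact p = 0.5), with Car2 down (−1.63 ± 0.42) among 3, and 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.846). Fcgr3 and Car2 lost their calls without any library other than adult replicate 2 (edgeR adjusted p at most 0.224 and 0.207). Stromal markers summed to 358 ± 32.8 and 386 ± 8.08 CPM (exact p = 0.4), mostly Pecam1 (0.12 ± 0.11) with little Acta2 (0.98 ± 0.69), and the CD8 genes to 34.2 ± 2.68 and 36.5 ± 4.97 (exact p = 0.6), mostly Cd8b1 (0.068 ± 0.18), as Cd8a was too low to test. With fewer than 3 tested members, these last lists and the sex-linked genes were not tested as lists.

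All 6 libraries carried Xist, the RNA of the inactive X chromosome, at 449, 362 and 479.6 CPM in adult and 669, 591 and 576 in infant cells (log2 fold change 0.51 ± 0.12, edgeR adjusted p = 0.0271). The call was lost without adult replicate 1 or any infant library (adjusted p at most 0.147). The 7 Y-linked genes examined had 0 counts in 4 libraries and 1 count each in infant replicates 2 and 3.

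By camera with a preset correlation, 12 of 36 lists passed, 7 down and 5 up, while 0 passed with an estimated correlation (1 at an unadjusted p under 0.05, the NF-kB targets) and 5 by the rotation test fry. The 5 were MHC class I, NF-kB, maturation, ribosomal protein and natural killer lists (fry adjusted p = 0.0109, 0.0109, 0.0109, 0.0456 and 0.0456). The median, mean and camera direction of a list differed in sign for 8 lists that did not pass: memory and effector (median −0.032, mean −0.011, upward), respiratory chain (−0.0021, −0.0085, upward), apoptosis (−0.0052, 0.039, upward), T helper 1 (−0.12, 0.077, downward), T helper 2 (−0.059, 0.81, upward), fetal (−0.059, 0.32, upward), glucocorticoid (−0.13, 0.0025, downward) and erythroid (0.79, −0.0087, upward). Except for the erythroid list, these medians moved by more than 1.5 times or changed sign without a single library.

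**Figure D4:**
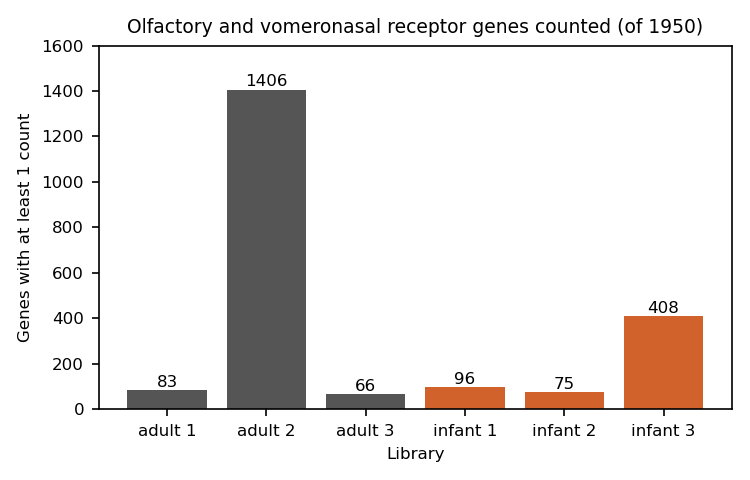
Bars give, for each of the 6 libraries, how many of 1950 olfactory and vomeronasal receptor genes had at least 1 count, with adult libraries in grey and infant libraries in orange. Adult replicate 2 had 1406 such genes and the other libraries 66 to 408.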

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

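The test of RNA from other cells was chosen after the result was seen, and the test of genomic DNA before.

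Adult replicate 2 had a count at 1406 of 1950 olfactory and vomeronasal receptor genes, which lymphocytes do not use, against 66 to 408 in the other 5 libraries, with infant replicate 3 the next highest. It had the smallest total of the 6 libraries, 3421253 counts, and the most genes with a count, 36373. RNA of other cell types was argued against by the 11 most abundant transcripts of other cells. Haemoglobins, Lyz2, S100a8, S100a9, immunoglobulin and collagen genes were among them, none of which T cells are known to make in quantity. They had 25 counts, a density 0.515 times that of untested autosomal protein-coding genes (95% Poisson interval 0.333 to 0.760). Their density of 0.955 counts per kb lay near the 1.02 of the receptor genes. Genomic DNA in the library may account for the pattern: over 11867 untested protein-coding genes its counts followed exon length with a Spearman rho of 0.636 across genes, which are not independent replicates, against 0.146 to 0.315 in the other libraries, and it had 1.77 counts per kb on the X chromosome and 1.85 on the autosomes, though 1.02 over the receptor genes. No biological explanation was tested, and without this library 488 genes were called, 331 of them among the 425.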

How the results depend on the processing

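No alternative here was chosen after the result was seen, apart from the length and GC corrections and the fit without adult replicate 2 and infant replicate 3. Of 78 named genes that passed, 42 kept their call and direction in all settings run on them, 14 lost it only when 1 library was left out, and 22 in other settings too or instead (10 unfiltered, 11 without the pair of libraries). The count of 425 genes was 428 with DESeq2 size factors, 459 with upper-quartile factors, 445 with library totals, 482 with a stricter filter, 441 after thinning, 368 without 5 gene classes, 451 and 432 after length and GC correction, 426 and 523 with limma-voom without and with quality weights, and 403 without adult replicate 2 and infant replicate 3 (280 shared). With no filter it was 550, and the median log2 fold change of the 39470 genes moved to −0.84. DESeq2 called 622 genes, 268 higher and 354 lower (417 shared). Fewer passed by construction at an adjusted p of 0.01 (162, 66 higher and 96 lower), with a 2-fold minimum (184, 85 and 99) and against 1.5-fold (78, 35 and 43). Leaving out 1 library, and so testing fewer samples, gave 139 to 488 genes, 55 to 217 higher and 84 to 271 lower, and 9 to 13 lists, while other settings of camera gave 10 to 15 lists. Estimating the correlation left 0 of the 12 lists. By fry 5 lists passed, among them the natural killer list, which was not among the 12. With the preset correlation, MHC class I, interferon-stimulated, cell-cycle, maturation and ribosomal protein lists passed camera in every setting run on them. NF-kB targets passed in all but the unfiltered one (adjusted p = 0.0780). By fry the interferon-stimulated and cell-cycle lists did not pass (fry adjusted p = 0.104 and 0.155). Beyond leaving out 1 library, the thymic emigrant list was lost with the stricter filter and thinned (0.274 and 0.0767), variable segments with the stricter filter and without the pair of libraries (0.0557 and 0.215), Myc targets without the pair (0.341), and the GTPase and cholesterol lists unfiltered (0.422 and 0.370) and without the pair (0.108 and 0.0827). Lists that did not pass in the main test passed in some settings: immediate-early genes with DESeq2 size factors, upper-quartile factors, library totals and the stricter filter (0.0498, 0.0464, 0.0467 and 0.0257), GIMAP genes with upper-quartile factors, library totals and without the pair (0.0464, 0.0367 and 0.0123), natural killer markers with library totals and thinned (0.0467 and 0.0262), gut-homing and histone genes without the pair (0.0270 and 0.0440), and respiratory chain, mitochondrially encoded, glycolysis and apoptosis genes unfiltered (0.00209, 5.86e-05, 0.0453 and 0.0283). The first component carried 46.1% of the variance over the 500 most variable genes. With the replicate number as a block 326 genes were called (129 higher, 197 lower, 310 shared) and 12 lists, but same-numbered libraries did not deviate together (r = −0.047, −0.011 and −0.092), so the numbers do not pair the mice. A change of sign occurred in 23 cases for genes and in 2 for shares, none past the test, and the cause was not tested. Over the leave-one-out fits the log2 fold change ran from −0.16 to 0.12 for Icos, −0.24 to 0.12 for Bst2, −0.094 to 0.16 for Egr2, −0.13 to 0.065 for Sh2d1a, −0.17 to 0.080 for Trp53 and −0.034 to 0.14 for Cd8b1. Unfiltered, Icos had 0.022, Bst2 0.023 and Cd3e 0.0032; thinned, Icos had 0.014 and Egr2 −0.035; with length correction Bst2 had 0.022. Without adult replicate 2 and infant replicate 3, Bst2 had 0.22, Cd3e 0.0016, mt-Co1 −0.0045 and Tgfbr2 −0.0087. As median log2 CPM, the erythroid and stromal shares differed by −0.22 and −0.58. Lin28b, Il1rl1, Cd24a and Cd8a did not pass the filter on low counts and were not tested.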

Other observations

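The genes of the next 2 paragraphs were chosen after their values were seen. So were the tests of the ribosomal protein genes and of handling, while the tests of the X-linked genes and of other splits were chosen before.

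Several abundant lymphocyte genes outside the lists were lower in infant cells. AW112010, an interferon-induced transcript of lymphocytes, had a log2 fold change of −1.90 ± 0.14 (SE, edgeR adjusted p = 2.49e-06, 3 libraries per age), and Art2b, an ADP-ribosyltransferase gene of mature T cells, of −1.78 ± 0.17 (adjusted p = 3.72e-05). Socs3, a feedback inhibitor of cytokine signalling, had −1.77 ± 0.19 (adjusted p = 1.35e-04), Als2cl −1.18 ± 0.11, and the transcription factor gene Zbtb20 −1.22 ± 0.15. Ltb, which encodes lymphotoxin beta, had −0.84 ± 0.10 (adjusted p = 2.69e-04), and Gpr183, an oxysterol receptor that guides lymphocytes within lymph nodes, −0.84 ± 0.13.

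Higher in infant cells were Acsbg1, an acyl-CoA synthetase gene (2.06 ± 0.19, edgeR adjusted p = 3.50e-05), and Itm2a, a membrane protein gene linked to thymocyte selection (1.11 ± 0.11, adjusted p = 5.18e-05). The tetraspanin gene Cd81 (1.08 ± 0.15), the G1 kinase gene Cdk6 (1.17 ± 0.17) and the cytokinesis motor gene Kif23 rose too, the last by 1.33 ± 0.18. Dpp4, the surface peptidase CD26, rose by 0.88 ± 0.14 and Cd86, a costimulatory ligand, by 1.38 ± 0.23. These 14 genes kept their calls without any single library and in all other settings run on them.

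The lower ribosomal protein RNA in infant cells had a median log2 fold change of −0.34. The background of adult replicate 2 was argued against, since the median was −0.31 without that library (camera adjusted p = 2.26e-11). A trend in the GC content of each gene's longest annotated transcript, which need not be the one made, was argued against as well. The lowest median among 10000 random lists matched on expression and that GC content was −0.0955. Among lists matched on expression and exon length it was −0.119. Exon length here spans all annotated exons of a gene (median 1754.5 bases in the list), which can exceed the length of the transcripts made. That comparison therefore cannot decide on a trend in transcript length. The tests also leave open other properties that ribosomal protein transcripts share, and the list's call was lost with an estimated correlation. A difference of age in the cells remains open and untested, as one candidate explanation.

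Nr4a1, Egr1 and Cd69, which respond to T cell receptor signals, were higher in infant cells. Handling of the cells before lysis may raise such genes, and could raise the other immediate-early and heat-shock genes too. These had a median log2 fold change of −0.31 with 4 members down and 0 up, though 5 of 17 had a positive change. The list did not pass (camera adjusted p = 0.0507), and Nfkbia, 1 of the 4, also belongs to the NF-kB targets that fell. A fall of other origin could hide a rise, so these values do not decide on handling. Without adult replicate 2 the changes were 0.78, 0.74 and 0.49 for Nr4a1, Egr1 and Cd69 (edgeR adjusted p = 0.0105, 0.0122 and 0.0484). In a fit chosen after the result was seen, without infant replicate 3 as well, Cd69 had 0.44 and did not pass (adjusted p = 0.103), while Nr4a1 and Egr1 passed (adjusted p = 0.0332 and 0.0385). Stronger receptor signals in the infant cells, or a larger share of recently activated cells, stay open as hypotheses that were not tested.

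A hypothesis that higher Xist in infant cells went with lower output of X-linked genes was not borne out: the median log2 fold change of 346 X-linked genes minus that of 11079 autosomal genes was 7.68e-04 (exact permutation test over libraries, p = 0.9), with 5 X-linked genes up and 6 down.

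With 3 libraries per age there are 10 splits, too few for a share under 0.05. The real split called 425 genes with edgeR, 1 of the 10 to call so many, and the highest of the other 9 called 0, with 291 to 533 genes at an unadjusted p under 0.05 against 2018. Each of the other 9 splits mixes the ages within both groups, so the age difference adds to their residual spread. Few calls follow from that design, and the splits cannot decide whether 425 exceeds chance.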
